A study of Caenorhabditis elegans with 2 samples.

How the data were processed

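Peak lists of eGFP-tagged ZTF-11 ChIP-seq from whole L4 larvae were used, for 1 group of 2 biological replicates. Per the labels, the fragment size range was 150 to 350 bp. The replicates were numbered as in the labels. There were 8 lists, 4 in each of the builds ce11 and ce10. Per the descriptions deposited with the lists, relaxed peaks were called by the authors on each replicate and on the pooled replicates against control alignments, and an IDR-thresholded list was made from these. The peak caller, its version and settings and the aligner are not given in the sources used here. The control alignments were not analysed here.

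For each peak the authors gave a signal value, whose scale is not stated, so it was used only to describe and rank peaks within a list. The deposited lists also hold the −log10 of a q value. It reached 2.12 in the pooled list and 0.629 in replicate 1, and ran from 2.58 to 3.57 in replicate 2, so it was not used to select peaks across lists. By this column no replicate 1 peak and every replicate 2 peak would pass a q of 0.05. Whether replicate 1 failed or the column was computed differently in each list is not known, so results for replicate 1 alone carry this doubt. Results from the pooled and thresholded lists, which were made from both replicates, carry it too. The p value column held a placeholder throughout all 8 lists and was not used. The pooled and replicate 1 lists held 30000 peaks each in both builds. The lists hold no read counts, so depth is unknown and no interval rests on it.

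Positions are given in ce11, counted from 1, with genes from Ensembl release 115 (WBcel235, the same coordinates) and sequence from the RefSeq genome. Lists in ce10 were used only for counts, and no coordinates were converted. The promoter window ran from 1000 bp upstream to 200 bp downstream of each annotated 5′ end. Summits outside promoters of protein-coding genes were classed as exon, intron or intergenic. Of 2554 gene symbols in the 25 lists, 2543 matched the annotation; 11 were left out. A peak was assigned to genes with the summit in the promoter window, else to the gene body it lay in, else to the nearest 5′ end.

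Overlap of the 1000 strongest peaks was set against 1000 random placements within chromosomes (one-sided). Classes of summits were set against 10000 placements (two-sided). Counts per chromosome were tested with an exact binomial test, and gene lists with Fisher's exact test against all other protein-coding genes. Lists were also tested by mean percentile rank of promoter signal against 100000 random lists, and called when the adjusted p was under 0.05 and both replicates were on the same side of 50. Correlations across peaks used 100000 pairings. Sequence within 100 bp of summits was compared with positions 1000 bp to either side by Fisher's exact test, and G and C content by sign permutation. Fisher's exact test took summits and flanks as independent, although each summit brought its own flanks. Adjusted p are Benjamini-Hochberg values. Mitochondrial peaks were left out of tests on the nuclear genome and kept in the overlap of the replicates, with nuclear peaks alone as an alternative. With 2 replicates and 1 group, no test between conditions was made.

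The tests, gene lists and the rule for named genes were set before the data were examined. The rule takes genes assigned to the 25 strongest thresholded peaks, members of a list with a peak in the window and the highest members of each called list (up to 4 per list), *ztf-11* and *unc-119*. Alternatives were the ce10 lists, the peaks at or above the median signal, other numbers of top peaks and overlap rules, promoter windows of 500 and 100 bp or 2000 and 500 bp, other backgrounds, motif lengths and distances, windows of 5 and 50 kb around the transgene loci, and each replicate alone. Splits by X and autosomes, the kinds of small RNA gene, G and C content, nuclear peaks alone and ranking at like window length were added after the data were seen.

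The tests were checked on simulated data. At 47 summits, promoter placement gave p under 0.05 in 5% of 40 sets with no excess. It did so in 100% of 40 sets with a share of 0.7 of the summits planted at promoters, and no smaller excess was simulated. For lists of 25 genes, the rank test did so in 5% of 200 unchanged sets and 88.5% of 200 sets raised by 20 percentile points. The simulated ranks held no ties and their p was not adjusted, so 88.5% is not the sensitivity of a call in these data. A 6-mer planted at 30% of 47 summits was found in 90% of 10 sets. There summits and controls were drawn alike from random positions, without the difference in G and C content seen in these data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.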

Results

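Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate the zinc finger protein ZTF-11 in the genome of *Caenorhabditis elegans*. ZTF-11 belongs to the Myt1 family of C2HC zinc finger transcription factors, which are known for repressing non-neuronal genes during neurogenesis. Whole L4 larvae of both sexes were used, from a strain that carries an integrated transgene of ZTF-11 fused to the green fluorescent protein eGFP, with a copy of *unc-119* as its marker. There was 1 group with 2 biological replicates, and no second condition, so the data answer where the factor was found and how far the replicates shared it. The peak lists give no read counts, so the depth of each library is unknown. Intervals below cover counting error only.

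The thresholded list held 47 peaks in the ce11 genome build, each 280 bp wide, with signal values from 27.2 to 77.1. It was made by the authors with a threshold on the irreproducible discovery rate (IDR). All 47 were the 47 strongest of the 30000 relaxed peaks called on the pooled replicates. The lists for the older ce10 build held 60 thresholded peaks. The relaxed list of replicate 1 held 30000 peaks and that of replicate 2 held 22869.

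Chromosome X carried more of the thresholded peaks than its length accounts for. It held 20 of the 47, or 42.6% (exact 95% interval 28.3 to 57.8), where its share of the nuclear genome is 17.7% and 8.31 peaks would match it (exact binomial test, two-sided, adjusted p = 0.00037 over 6 chromosomes). X also held 16 of the 25 strongest peaks. Chromosome V held 3 peaks where its length gives 9.81 (exact binomial test, adjusted p = 0.0335). Chromosomes I, II, III and IV held 2, 9, 10 and 3 peaks, with exact binomial adjusted p of 0.0781, 0.419, 0.165 and 0.0782. The low count on V passed in the 24 strongest peaks, with 0 of them (exact binomial test, adjusted p = 0.0153). It did not pass in the ce10 list, where V held 6 of 60 peaks (exact binomial test, adjusted p = 0.115), or in the 47 strongest peaks of either replicate alone (adjusted p = 0.315 in replicate 2 and 0.104 in replicate 1).

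**Figure D1:**
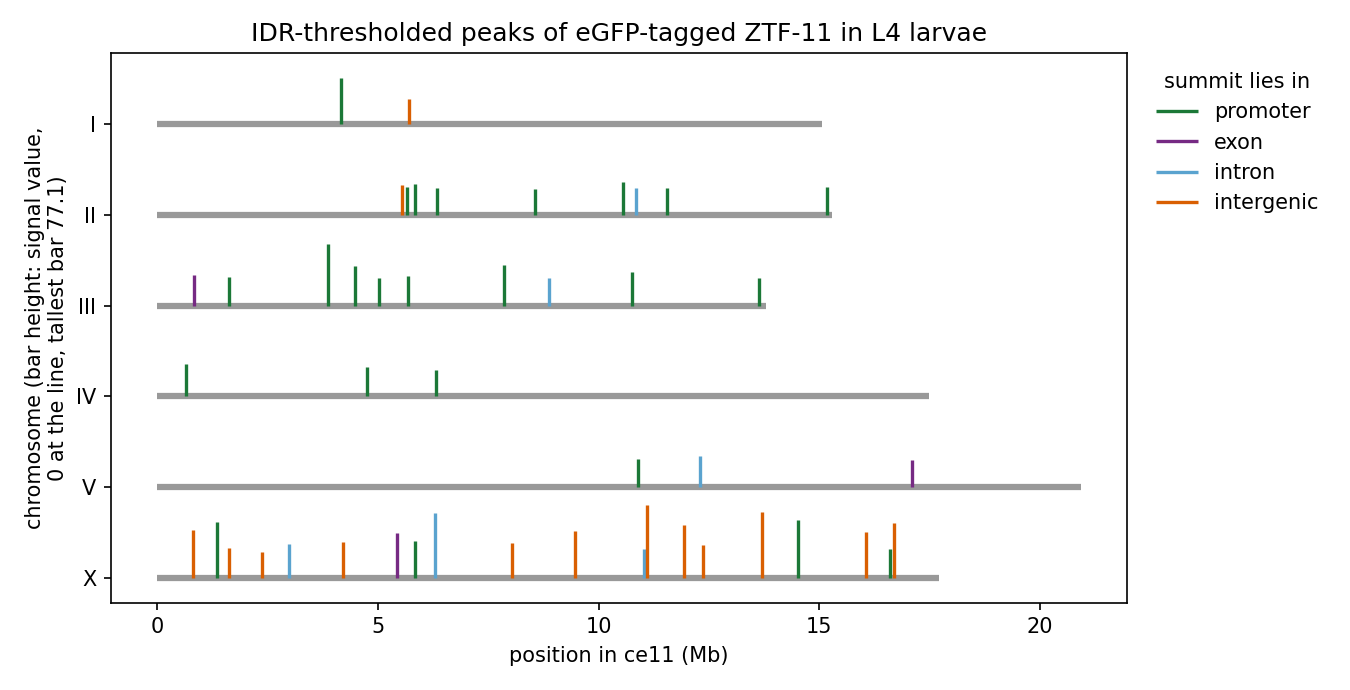
Thresholded peaks along the 6 nuclear chromosomes in ce11, with position in Mb on the x axis. Each bar is 1 peak, its height is the signal value (tallest 77.1) and its colour is the class of its summit; X held 20 of the 47 peaks and 12 of the 14 intergenic ones.

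The strongest peak of the list lay between genes on X, at 11094064 to 11094343, with a signal of 77.1. Its summit was 3982 bp downstream of the nearest annotated 5′ end, that of W02H3.3. The next lay at 13700716 to 13700995 on X, with a signal of 70.2, 6051 bp upstream of K02D3.1. A peak with a signal of 68.7 at 6296390 to 6296669 lay in an intron of *mom-1*, which encodes the Porcupine protein needed for Wnt secretion. Between genes on X there were also peaks nearest to F22H10.2 (signal 58.1), F55G7.5 (55.4), *gtr-1* (50.5), ZK899.6 (49.1), T27A8.7 (48.7), F20B6.9 (37.9) and F19H6.5 (34.8). The peak at 8036242 to 8036521 had a signal of 37.3 and lay 4931 bp upstream of *xol-1*, the switch gene of sex determination. One X peak lay in an exon of the polyketide synthase gene *pks-1* (signal 47.7), and 1 in an intron of Y41G9A.17 (signal 35.8). In promoter windows on X, the peaks were at *nspc-17* (signal 61.3), the insulin-like peptide gene *ins-39* (59.5), the Pumilio family gene *puf-9* (39.2) and *ain-1* (30.1), which encodes a GW182-family protein of the microRNA pathway.

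On the autosomes the strongest peak lay at the promoter of *rpl-3*, which encodes a protein of the large ribosomal subunit. It spanned 3867417 to 3867696 on chromosome III, with its summit 297 bp upstream of the 5′ end and a signal of 65.1. Among the 25 strongest peaks, further ribosomal protein genes with a peak in the promoter window were *rpl-35* (signal 43.2), *rps-1* (42.5, a summit shared with *ifet-1*, whose product binds the translation factor eIF4E) and *rpl-15* (33.97, shared with K11H12.8). The second strongest autosomal peak lay at 4172019 to 4172298 on chromosome I, with a signal of 49.2. It was 570 bp upstream of *egg-5*, which acts in the oocyte-to-embryo transition, and within 300 bp of *sls-2.4*, a small nuclear RNA gene for a spliced leader. Other autosomal peaks among the 25 strongest lay at the promoters of *tasp-1* and K01G5.10 (signal 35.8) and of *cdc-48.1* (35.4), which encodes an AAA ATPase, in an exon of *dos-3* (32.9) and in an intron of *frm-7* (32.7). The latter summit was within 300 bp of the small nucleolar RNA (snoRNA) genes C51F7.3 and C51F7.4.

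Summits lay at promoters more often than random placement gives. Of the 47, 24 lay from 1000 bp upstream to 200 bp downstream of an annotated 5′ end of a protein-coding gene, or 51.1% (exact 95% interval 36.1 to 65.9). Random positions on the same chromosomes gave 24.8% ± 6.18 (SD of 10000 placements; two-sided permutation p = 0.0004, adjusted p = 0.0009 over 9 classes). Outside promoters, 3 summits lay in exons, where placement gave 21.5% of summits against 6.38% observed (permutation test, adjusted p = 0.0202). Introns held 6 summits, 12.8% against 27.1% (permutation test, adjusted p = 0.0513). Intergenic sequence held 14, 29.8% against 26.8% (permutation test, adjusted p = 0.83). In a split chosen after the data were seen, autosomal summits lay at promoters more often than X summits: 20 of 27 (74.1%) against 4 of 20 (20%; Fisher's exact test, two-sided, p = 0.000355). On X, random placement gave 21.8% (permutation p = 1). The 12 intergenic X summits lay 999 to 6051 bp from the nearest 5′ end. The promoter excess did not pass the test with a window of 2000 and 500 bp, in the 24 strongest peaks, or in the 47 strongest nuclear peaks of replicate 1 alone (34%, permutation p = 0.157); those of replicate 2 alone gave 66%.

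Promoter windows of non-coding RNA genes held 18 of the 47 summits, 38.3% against 13.4% ± 4.9 from placement (permutation test, adjusted p = 0.0009). By kind of gene, a split chosen after the data were seen, windows of snoRNA genes held 9 summits against a mean of 0.17 from placement and those of small nuclear RNA genes held 3 against 0.0423 (permutation test, p = 0.0002 for each, the smallest that 10000 placements give). Windows of microRNA genes held 1 summit and those of transfer RNA genes held 0. Within 300 bp of a gene body, 9 summits lay beside a small RNA gene. They were near *sls-2.4*, *sls-2.1* and *sls-2.2*, near a microRNA gene of the *mir-90* locus, and near the snoRNA genes F54E7.10, Y53F4B.48, M106.6, T19B4.8 and the pair at *frm-7*. The genes in that list outside the 25 strongest peaks were named after their values were seen. Within 300 bp, 5 summits lay beside snoRNA genes. The peak near F54E7.10 also lay in the promoter window of a ribosomal protein gene, so it counts in both sets. Windows of snoRNA genes can overlap promoters of protein-coding genes, which uniform placement did not allow for.

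Of the 25 gene lists fixed in advance, ribosomal protein genes and chaperones had more promoters with a thresholded peak than other genes. A peak lay at 6 of 81 ribosomal protein genes, 7.41%, against 29 of 19892 other genes, 0.146% (Fisher's exact test, two-sided, adjusted p = 1.36e-07). Among the 47 strongest nuclear peaks of a single replicate the count was 3 of 81, in replicate 2 (Fisher's exact test, adjusted p = 0.0132) and in replicate 1 (adjusted p = 0.00105). The 4 with the highest signal were *rpl-3*, *rpl-35*, *rps-1* and *rpl-15*. Among chaperones 2 of 28 had a peak (Fisher's exact test, adjusted p = 0.0137). These were *hsp-60*, which encodes the mitochondrial chaperonin (signal 30.2), and *dnj-13*, a DnaJ-type co-chaperone gene (28.6). The chaperone result did not pass with the window of 500 and 100 bp, in the 24 strongest peaks, or in either replicate alone. A single member had a peak in the heterochronic list (*ain-1*; Fisher's exact test, adjusted p = 0.287), in RNA processing and translation factors (*iff-2*, an eIF5A gene, signal 27.2; adjusted p = 0.403) and among neuropeptide genes (*ins-39*; adjusted p = 1). The other 20 lists had 0 members with a peak. They included proneural and neurogenesis regulators (0 of 25 genes), pan-neuronal genes (0 of 26), neuron type selectors (0 of 25) and Notch pathway genes (0 of 24). With the 1000 strongest pooled relaxed peaks in place of the thresholded list, 6 of 26 pan-neuronal genes had a peak, 23.1% against 2.18% of other genes (Fisher's exact test, adjusted p = 0.000148), as did 4 of 20 heterochronic genes, 20% (adjusted p = 0.00357). There 11 of 81 ribosomal protein genes, 7 of 38 RNA processing and translation factors and 5 of 28 chaperones had a peak (Fisher's exact test, adjusted p = 4.06e-05, 0.000148 and 0.00207), and chemoreceptor genes fewer than other genes, 9 of 1071 (adjusted p = 0.00357). Median promoter windows of pan-neuronal and heterochronic genes were 1366 and 2404 bp, against 1201 bp for all genes. In that setting 0 of 25 proneural and neurogenesis regulators, 1 of 25 neuron type selectors and 0 of 24 Notch pathway genes had a peak. In the thresholded list 35 genes in all had a peak at the promoter, so a depletion of lists of this size was not detectable.

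To use weaker peaks as well, each of 19973 protein-coding genes was ranked by its highest pooled relaxed signal in the promoter window, which held a peak for 7804 genes. By this measure 6 lists stood high and 3 low in mean percentile rank, with both replicates on the same side of 50. Translation genes were among the high ones. RNA processing and translation factors had a mean percentile of 71.1 ± 4.14 (SD of random lists of the same size; permutation test, adjusted p = 0.000125), with *iff-2*, *ife-3*, *eef-1G* and *eef-1A.2* at the top, although *ife-3* had no replicate 1 peak in its window. Ribosomal protein genes had 66.3 ± 2.81 (permutation test, adjusted p = 0.000125), and chaperones 67.1 ± 4.82 (adjusted p = 0.00392), led by *hsp-60*, *dnj-13*, *cct-1* and *hsp-1*. These 3 lists also stood high when genes were ranked among genes with promoter windows of like length (permutation test, adjusted p = 0.0035, 0.0005 and 0.019), a setting chosen after the data were seen.

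The other 6 lists lost their call among genes with windows of like length. Heterochronic genes, which time larval development, had 75.8 ± 5.69 (permutation test, adjusted p = 0.000125), led by *ain-1*, *lin-14*, *nhl-2* and *hbl-1*. Their windows had a median of 2404 bp, against 1201 bp for all genes, and the mean was 65.3 among genes of like length (permutation test, adjusted p = 0.0611). Pan-neuronal genes had 64.8 ± 4.98 (permutation test, adjusted p = 0.0151), led by *egl-3*, *rbf-1*, *snb-1* and *unc-44*, and 56.2 at like length (adjusted p = 0.532). Cell cycle genes had 62.4 ± 4.49 (permutation test, adjusted p = 0.0208), led by *pcn-1*, *mcm-4*, *bub-1* and *cdk-4*, and 60.5 at like length (adjusted p = 0.115). Of the low lists, histone genes had 35.8 ± 3.59 (permutation test, adjusted p = 0.0002), with 5 of 50 holding any relaxed peak; *his-37*, *his-24*, *his-31* and *his-42* ranked highest. Chemoreceptor genes of the 7-transmembrane families had 44.2 ± 0.757 (permutation test, adjusted p = 0.000125), with *srh-269*, *srh-2*, *srh-16* and *str-115* highest. C-type lectin genes had 45.7 ± 1.64 (permutation test, adjusted p = 0.0208), with *clec-80*, *clec-95*, *clec-31* and *clec-142* highest. Of these genes, *srh-269*, *srh-16*, *str-115* and *clec-95* had no replicate 2 peak in their windows. At like length these 3 lists stood at 42, 48.3 and 50 (permutation test, adjusted p = 0.115, 0.115 and 0.996). The low rank of histone genes rested on replicate 1, with 35.4 in replicate 1 alone and 48.9 in replicate 2 alone (permutation test, adjusted p = 0.000167 and 0.789). Cell cycle and pan-neuronal genes did not pass in replicate 1 alone (55 and 60.9; permutation test, adjusted p = 0.494 and 0.0939), and C-type lectin genes passed in neither replicate alone (46.3 in replicate 1 and 48.8 in replicate 2; permutation test, adjusted p = 0.0894 and 0.522).

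The remaining 16 lists did not pass the test. Of these, the neural and homeobox lists stood near the middle, with proneural and neurogenesis regulators at 50.1 ± 5.08, neuron type selectors at 51 ± 5.07, homeobox ceh genes at 51.5 ± 3.2 and neuropeptide genes at 52 ± 2.14. Signalling and chromatin lists stood at 51.1 ± 5.17 (Notch pathway), 57.2 ± 5.19 (Hox and Wnt genes) and 57.1 ± 4.41 (chromatin regulators). Tissue lists stood at 56.6 ± 4.71 (body wall muscle), 50.2 ± 6.14 (pharynx), 51.5 ± 4.64 (intestine), 44.6 ± 4.21 (epidermis and cuticle), 45.6 ± 5.29 (glia), 42.7 ± 4.28 (germline and meiosis) and 40.8 ± 4.56 (major sperm protein genes). Collagen genes stood at 47.9 ± 2.02 and nuclear hormone receptor genes at 50.4 ± 1.55. Across all 19973 genes, which are not independent replicates, promoter signal of the 2 replicates had a Spearman rho of 0.0983.

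**Figure D2:**
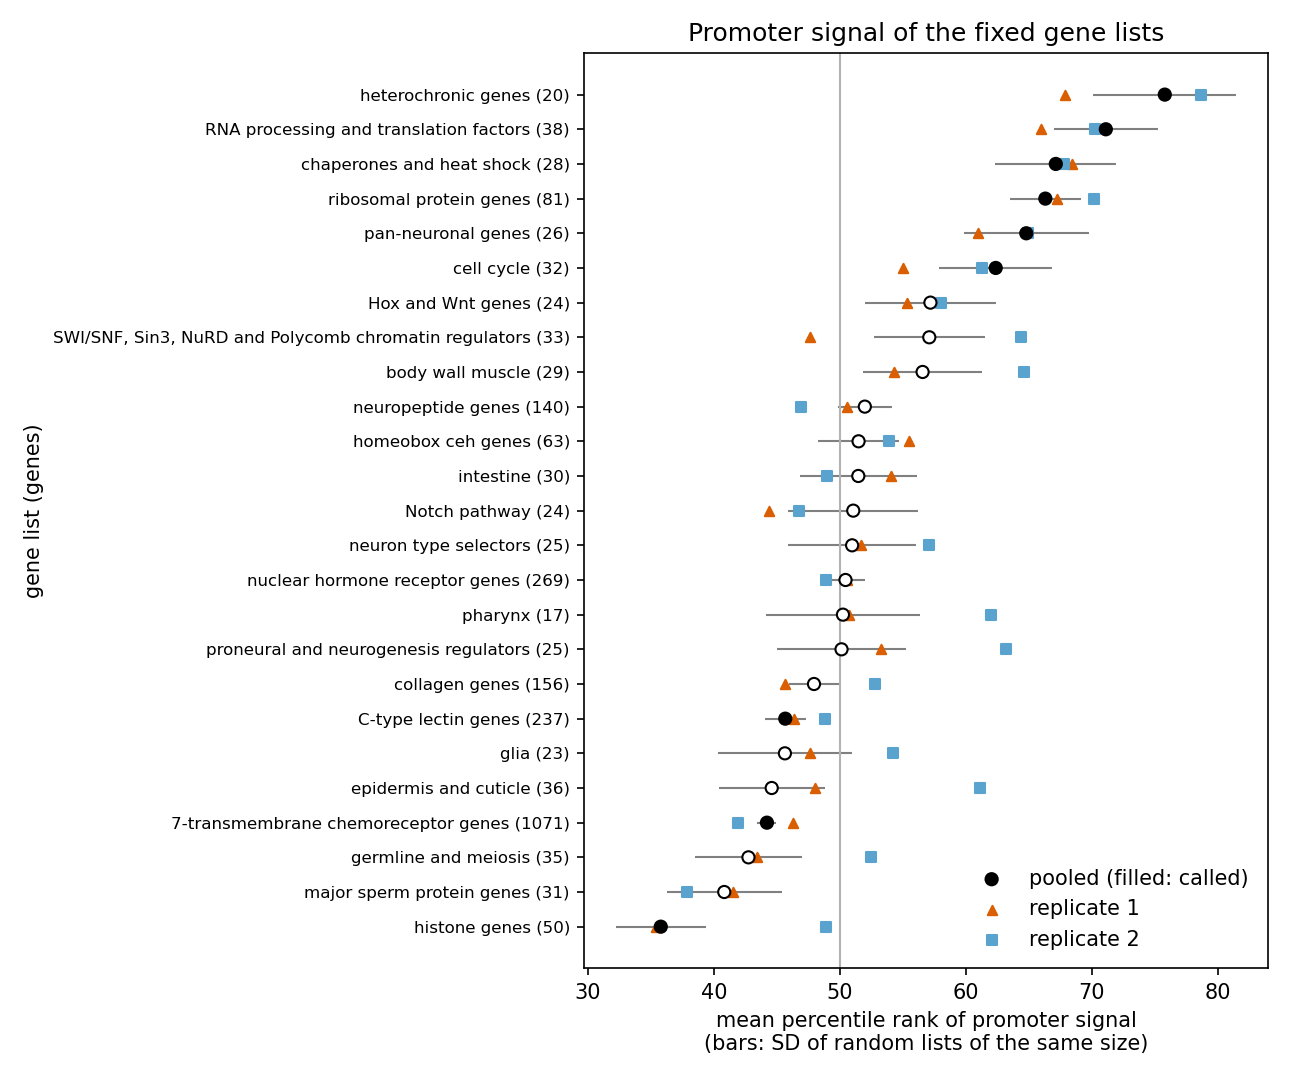
Mean percentile rank of promoter signal for each of the 25 gene lists, with the number of genes in parentheses. Circles are the pooled list (filled where called), triangles replicate 1 and squares replicate 2; bars are the SD of random lists of the same size. RNA processing and translation factors stood at 71.1 and histone genes at 35.8.

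The replicates shared a small part of their strongest peaks, more than random placement gives. Placement was uniform along each chromosome and did not allow for regions prone to peaks in any library. The excess alone is therefore not evidence of shared binding by the factor. Of the 1000 strongest peaks of replicate 1, 44 (4.4%) overlapped one of the 1000 strongest of replicate 2 by 1 bp or more, against 0.593% ± 0.247 for random placement (SD of 1000 placements; one-sided permutation p = 0.000999, the smallest they give). Among the 200 strongest, the share was 9% against 0.111% for placement, and among the 5000 strongest 4.68% against 2.91% (permutation p = 0.000999 for each). In replicate 1, 14 of the 200 strongest peaks were mitochondrial, and replicate 2 held no such peak for them to overlap. Of the 47 thresholded peaks, 45 overlapped a relaxed peak in replicate 1 and 45 one in replicate 2. The X peaks near *fbxb-58* and T24D8.6 had none in replicate 2, and the X peak in *ldb-1* and the chromosome V peak at *sec-61.G* had none in replicate 1. These 4 were named after their values were seen. The overlapping peak ranked within the 1000 strongest nuclear peaks for 34 of the 47 in replicate 1 and 40 in replicate 2. Others overlapped only weak peaks, such as rank 26275 of replicate 1 at *ain-1* and rank 7045 of replicate 2 near ZK899.6. An overlap with a relaxed list is therefore weak evidence that a replicate holds the peak. Across the 47 peaks, signal in the 2 replicates had a Spearman rho of -0.207 (permutation p = 0.161, adjusted p = 0.376 over 5 sets of peaks) and a Pearson r of -0.112 (permutation p = 0.455), or -0.121 without the 2 peaks farthest from the median of replicate 1. Peaks are not independent replicates, and these were selected by their pooled signal.

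**Figure D3:**
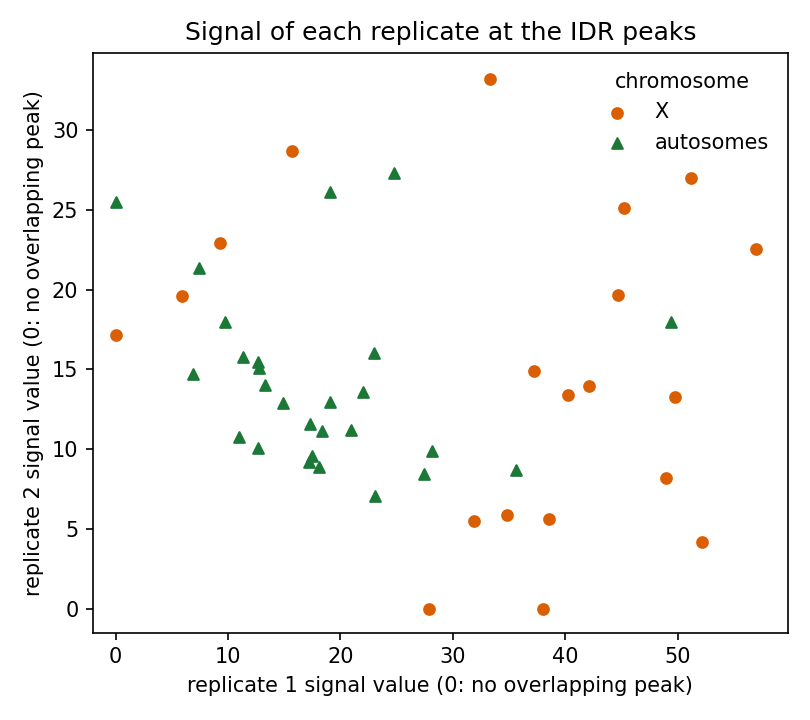
Signal value in replicate 1 (x axis) and replicate 2 (y axis) at the 47 thresholded peaks, with X as circles and autosomes as triangles; 0 marks a peak with no overlap in that replicate. Signal of the 2 replicates had a Spearman rho of -0.207 across the peaks.

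The summits were searched for the core sequence that Myt1-family proteins are known to bind. The 7-mer AAAGTTT, on either strand, lay within 100 bp of 2 of 47 summits (4.26%) and of 19 of 94 positions 1000 bp to either side (20.2%; Fisher's exact test, two-sided, p = 0.0118), so it was less frequent at summits. With the shorter core AAGTT the shares were 44.7% and 58.5% (Fisher's exact test, p = 0.152) and the difference did not pass. For the 7-mer it passed within 200 bp, at 14.9% of summits and 31.9% of flanks (Fisher's exact test, p = 0.0415), and in replicate 2 alone, at 0 of 47 summits and 16 of 94 flanks (p = 0.00133). It did not pass within 50 bp (Fisher's exact test, p = 0.219), against pooled peaks of median rank (p = 0.0905), in replicate 1 alone (p = 0.18) or on autosomes alone, where the 7-mer was at 7.41% of summits and 13% of flanks (p = 0.71). In a comparison added after the data were seen, summits were richer in G and C than their flanks, 44.6% ± 6.42 against 37.8% ± 5.57 (SD over 47 peaks; permutation test, adjusted p = 1.5e-05). AAAGTTT is rich in A and T, and how far its lower share at summits reflects this difference was not tested. A search of all 6-mers found 17 of 2073 that differed between summits and flanks, 16 of them more frequent at summits. The strongest were CGCACA, at 14 summits and 0 flanks (Fisher's exact test, adjusted p = 9.8e-05), CGCGCA, at 13 and 0 (adjusted p = 0.000184), and CTGCGC, at 14 and 1 (adjusted p = 0.00034). Split by chromosome after the data were seen, CGCACA led on the autosomes, at 11 of 27 summits and 0 of 54 flanks (Fisher's exact test, adjusted p = 0.0022). On X, CCCTTC and CTGCGC led, each at 12 of 20 summits and 0 of 40 flanks. Flanks were not matched to summits for G and C content or class, so how far these differences reflect base composition was not tested. CGCGCA and CTGCGC are also parts of the motif weighed below for the X peaks.

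Because the strain carries added copies of *ztf-11* and *unc-119*, peaks around both genes were counted. Within 20 kb of *ztf-11* (chromosome I, 9904303 to 9910545) there were 26 pooled relaxed peaks, against a median of 14 in 1000 random windows of the same length, at percentile 98.95. Replicate 1 gave 26 peaks (percentile 99.15) and replicate 2 gave 17 (percentile 88.1). Around *unc-119* (chromosome III, 10902641 to 10908935) there were 14 pooled peaks within 20 kb, at percentile 53.35, and the percentile was 36.65 within 5 kb and 43.2 within 50 kb. In replicate 1 alone *unc-119* had 9 peaks within 5 kb against a median of 5 (percentile 94.2), as many as *ztf-11* (percentile 93.4). No window around either gene held a thresholded peak.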

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

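The tests of coverage on X and of each replicate alone were chosen after the result was seen. The relaxed list of replicate 1 held 15 peaks on the mitochondrial genome. The only comparison that counted them was the overlap of the strongest peaks, which at 1000 peaks gave 4.4% with them and 4.4% without them. At 200 peaks the overlap without them was not computed. They made up 13 of the 20 strongest peaks of that list and 14 of its 200 strongest, with signal up to 1161 where its strongest nuclear peak had 56.9. The lists of replicate 2 and of the pooled replicates held 0 mitochondrial peaks.

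The first pattern weighed was the excess of thresholded peaks on X. Higher coverage of the whole chromosome as the sole cause is argued against by the share of X among all pooled relaxed peaks. That share was 18.9%, against 17.7% of the nuclear genome and below the lower bound of 28.3% for its share of thresholded peaks. The relaxed list reaches down to a −log10 q of 0.0352 and coverage itself was not measured, so a part played by coverage stays open. The excess was not carried by 1 replicate: X held 22 of the 47 strongest nuclear peaks of replicate 1 and 18 of those of replicate 2 (exact binomial p = 4.09e-06 and 0.000778). A candidate explanation is that these are sites where the dosage compensation complex is recruited to X. The motif used to test this, TCGCGCAGGGAG, was recalled from the literature on such sites and not checked against a source, so the reading depends on its being right. With at most 2 mismatches it lay within 100 bp of 12 of 20 X summits and 1 of 27 autosomal ones (Fisher's exact p = 2.47e-05), of 0 of 40 X flanks and of 0.4% of 2000 random X positions. CTGCGC (read on the other strand) and CGCGCA, found above in the k-mer search of the same summits, are parts of this motif. CTGCGC alone lay at 12 of 20 X summits and 0 of 40 X flanks, so the motif count is not independent of that search. Whether the tagged protein binds there, or such sites are enriched in any immunoprecipitation, was not tested, and the control alignments were not analysed here.

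The second pattern was the set of 14 thresholded peaks at ribosomal protein promoters or beside small RNA genes. Reads shared between exact copies are argued against as the main source: 0% of the 14 peaks had most of their 36-mers repeated in the genome, and 11 had none repeated. The other 3, beside *sls-2.4*, *sls-2.1* and *sls-2.2*, had 7.35%, 25.3% and 21.2% repeated, so shared reads as a part of these 3 peaks stay open. Copies that differ by a base were not searched for and the aligner is not known, so reads shared between such copies stay open for all 14. Direct binding to the Myt1-family core stays open, since AAAGTTT lay at 2 of 14 summits and 2 of 28 flanks (Fisher's exact p = 0.59), too few to decide. These genes are highly transcribed, and an enrichment of such promoters unrelated to the factor was not tested.

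The third pattern was the larger number of relaxed peaks around *ztf-11*. Extra copies in the integrated construct could raise it, and the excess would then end at the edge of the construct. The pooled count was at percentile 93.35 within 5 kb (9 peaks against a median of 5), 98.95 within 20 kb (26 against 14) and 99.95 within 50 kb (57 against 32), but these windows are nested, so they do not show where the excess ends. The extent of the construct is not given in the sources used here. At 100 to 200 kb from the gene there were 77 pooled peaks against a median of 60 in random places, at percentile 93.55. This lies between the 75th percentile, below which a local excess was to be read, and the 95th, from which a regional one was, so added copies and a peak-rich region cannot be told apart.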

How the results depend on the processing

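Splits by chromosome, nuclear peaks alone and ranking at like window length were chosen after the data were seen. The excess on X, the overlap of the replicates and the signal correlation kept their direction and side of the threshold in every alternative run for them. The median-signal list held 24 peaks by construction. The promoter share was 57.4% with the 2000 and 500 bp window, 41.7% in the stricter list and 20% on X alone, none past the threshold, and 34% to 66% in single replicates. Gene lists that differed from other genes in peaks at promoters numbered 1 with the 500 and 100 bp window, 1 in the stricter list, 6 with the 1000 strongest pooled peaks (chemoreceptor genes lower, 0.84% against 2.29%, the others higher) and 1 in each single replicate. The Myt1 7-mer was at 4.26% of summits within 50 bp or against pooled peaks of median rank, the 5-mer at 44.7% and the 7-mer at 7.41% on autosomes, none past the threshold; single replicates gave 0% to 12.8%. Called k-mers numbered 6 as 7-mers, from a larger number tested, and 3 on autosomes. Peak counts were at percentile 88.1 to 99.15 at *ztf-11* and 55.25 to 79 at *unc-119* within 20 kb in single replicates.

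Lists called by promoter signal numbered 3 at like window length and 6 to 12 elsewhere. Over 175 alternatives of single lists, 113 kept direction and side, 18 lost a call, 6 gained one and 38 changed direction, of which histone genes (58.2 among genes with a relaxed peak) was the only list called in the main setting. Of the others, epidermis was called high in replicate 2 alone (61.2, permutation test, adjusted p = 0.0133). Of the lost calls, 6 were at like window length. The others were histone genes with the narrow window (42.1) and the wide window (33.7), where replicate 2 lay above 50, and in replicate 2 alone; cell cycle genes with the wide window (58.3), among genes with a relaxed peak (59.5) and in replicate 1 alone; C-type lectin genes with the wide window (42.9, replicate 2 above 50) and in each replicate alone; pan-neuronal genes among genes with a relaxed peak (64.8) and in replicate 1 alone; and heterochronic genes among genes with a relaxed peak (67). Major sperm protein genes gained a call, as low, with the wide window (37.1), among genes with a relaxed peak (24.8) and in replicate 2 alone (37.9); proneural genes, body wall muscle and chromatin regulators gained one, as high, in replicate 2 alone. With the narrow window, pharynx was at 43.9, ceh genes 49.2 and neuropeptides 49.6. With the wide window, proneural genes were at 48.3, Hox and Wnt 49.7, pharynx 41.8, epidermis 52.9, collagens 51.9, nuclear receptors 49.7, ceh genes 46.8 and neuropeptides 48.5. Among genes with a relaxed peak, proneural genes were at 47.9, Notch 37, Hox and Wnt 48.3, pharynx 45, epidermis 66.6, germline 59.5, nuclear receptors 47.1, ceh genes 43.1 and neuropeptides 42.5. On autosomes, pharynx was at 48.8 and intestine 47.9. At like window length, proneural genes were at 48.5, neuron selectors 45.6, pharynx 43.1, collagens 51.1 and nuclear receptors 48.6. Single replicates gave 44.4 to 46.7 for Notch, 48.95 to 54 for intestine, 48 to 61.2 for epidermis, 47.6 to 54.2 for glia, 43.4 to 52.5 for germline, 45.6 to 52.8 for collagens, 48.9 to 50.6 for nuclear receptors, 46.95 to 50.6 for neuropeptides and 47.6 to 64.4 for chromatin regulators. The cause of these changes was not tested. Depth is unknown and its effect was not tested.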

Other observations

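The test of the X motif by place was chosen after the result was seen. The 12-bp motif lay at 7 of the 12 intergenic X summits and at 5 of the 8 X summits in promoters, exons or introns. Without a mismatch it lay at the strongest peak of the whole list, nearest to W02H3.3, and at the peak in an intron of Y41G9A.17.

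Each replicate's relaxed list covered a different part of the pooled one. Of the 30000 pooled peaks, 18391 (61.3%) overlapped a replicate 1 peak, 7510 (25%) a replicate 2 peak and 3001 (10%) both. The lists are unlike in size: the 30000 peaks of replicate 1 (median width 390 bp) covered 11.7% of the nuclear genome. The 22869 of replicate 2 (196 bp) covered 4.47%. Overlap under random placement was not computed for these shares, so how far they reflect list size is not known. Where found, thresholded peaks on X had a median rank among nuclear peaks of 11 in replicate 1 and 42.5 in replicate 2, and autosomal ones 165.5 and 106.

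With replicate 2 alone, 10 lists stood high in promoter signal and 2 low. Of these, 5 were not called in the pooled list. They were proneural and neurogenesis regulators (mean percentile 63.2; permutation test, adjusted p = 0.0154), body wall muscle (64.6; adjusted p = 0.0045), epidermis and cuticle (61.2; adjusted p = 0.0133), chromatin regulators (64.4; adjusted p = 0.00307) and, low, major sperm protein genes (37.9; adjusted p = 0.00307). With replicate 1 alone these 5 were at 53.3, 54.3, 48, 47.6 and 41.5, and none was called.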
